A study of Homo sapiens with 22 samples.

How the data were processed

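Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out for FOXA1 and ARNTL in the prostate cancer cell lines LNCaP and LNCaP-42D. Of the 22 samples, 20 had a peak list, in 10 groups of 2 replicates, and the 2 input DNA samples were not analysed here. Groups and replicate numbers were taken from the sample titles, because the cell line label names LNCaP also for the LNCaP-42D samples. Nothing in the labels says whether the 2 replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

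Per the submitters' processing notes, the tools were BWA and MACS2 and the genome build was hg19. Tool versions, the control sample given to the peak caller, the cut-off and any filter were not given in the sources used here. Each deposited list belongs to a single library, so peaks were called per library and not on pooled replicates. The lists have the narrowPeak layout, and the deposited columns were used as follows. The score of each peak, deposited by the authors as a whole number for display, was not used. The fold enrichment at the summit is the authors' ratio of signal over background and was used only to describe peaks or to group them by strength within a list. The deposited −log10 p and −log10 q are the authors' values for each peak, and −log10 q was used to rank or filter peaks within a list. The lowest deposited −log10 q in any list was 2.00. The summit offset was used only for the summit rule given below. Read numbers and coverage are not in the lists, so the sequencing depth of each library is unknown, and the number of peaks called cannot be separated from depth.

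Peaks on chromosomes 1 to 22, X and Y were kept. A reproducible region was the union of overlapping peaks of both replicates of a group, with a minimum overlap of 1 bp. A region was called gained when it was reproducible in the later state and neither replicate of the earlier state had a peak there, and lost in the reverse case. For each pair of states the counts were set beside those from the 2 other splits of the same 4 libraries into pairs. Each other split pairs 1 library of each state (or siRNA), so it counts only regions called in both. Its counts therefore depend on list length and are not those expected without a difference. A peak was placed at a FOXA1 region when it overlapped a reproducible FOXA1 region by at least 1 bp. The background for this share was obtained by shifting all peaks of a chromosome by a common random distance around that chromosome, in 100 shifts per library with a fixed seed.

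Peak numbers (on the log2 scale) and shares per library were compared over untreated, treated and resistant cells with an exact two-sided permutation test of the linear trend (the resistant minus the untreated mean), which has 90 arrangements and a smallest p of 0.0222. The siRNA comparisons used an exact two-sided permutation test within cell line, with 36 arrangements and a smallest p of 0.0556. Shares of ARNTL peaks on chromosomes 13 and Y were compared between the lines by permutation within siRNA condition, with 540 arrangements. A comparison of 2 libraries with 2 cannot go below 0.333 and was not tested. The 5 library-level tests were adjusted together by the Benjamini-Hochberg method. Sets of regions were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family (comparisons, cell lines or quartiles). Regions of a set of libraries are not replicates, so these tests describe the libraries at hand. Odds ratios have 95% intervals from the standard error of the log odds ratio, and shares of regions have 95% Wilson intervals. All of these intervals cover counting error only. Regions named in the text were the 3 best gained and the 3 best lost regions per comparison by mean within-list percentile of −log10 q, or a selection of these. For the siRNA comparison, siNT was the earlier state. The groups, tests, naming rule and alternatives were fixed before the data were examined, unless the text says otherwise. Shares of changed regions in the third state and counts by chromosome and 5 Mb window were not part of that plan. Nor were the strength quartiles for gained ARNTL regions at FOXA1 regions.

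The alternatives were a −log10 q of at least 5, lists of equal length, an overlap of at least 50% of the shorter peak, summits within 100 bp, omission of each replicate in turn and a replicate block. Other FOXA1 region sets and another rule for loss were tried too. For equal length, the peaks with the highest −log10 q were taken from each list, 56611 for FOXA1, 1955 for ARNTL in untransfected cells and 2586 for ARNTL after siRNA. No annotation or sequence of hg19 was used here, and coordinates were not converted between builds. Gene names, promoter shares, motif shares and gene lists are therefore not given, and regions are named by their hg19 coordinates, counted from 1.

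The code was tested on simulated data. With 2000 gained and 2000 lost regions placed among the 53754 reproducible FOXA1 regions of untreated cells, and with each list holding a region with a chance of 90%, all 1603 gained and all 1619 lost regions present in both lists of a state were recovered. A further 426 unchanged regions were called gained and 393 lost, because both lists of the other state had missed them. With 200 changed in each direction among 4390 ARNTL regions, all 160 gained and all 158 lost regions were recovered, and 28 unchanged regions were called gained and 34 lost. The real ARNTL lists agree less. Only 46.6% of the peaks of untreated replicate 2 and 31.3% of those of LNCaP siNT replicate 2 were in the other, shorter list. The simulation therefore checks the code and does not estimate false calls in the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.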

Results

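FOXA1 and ARNTL binding was mapped by ChIP-seq in LNCaP, an androgen-responsive human prostate cancer cell line, and in LNCaP-42D, an enzalutamide-resistant line. FOXA1 is a pioneer transcription factor that opens chromatin for the androgen receptor. ARNTL, also called BMAL1, is a core transcription factor of the circadian clock. Enzalutamide blocks the androgen receptor. The states compared were untreated LNCaP, LNCaP after 10 µM enzalutamide for 48 h, and LNCaP-42D kept in 10 µM enzalutamide. ARNTL was also mapped in treated LNCaP and in LNCaP-42D after non-targeting siRNA (siNT) or FOXA1 siRNA (siFOXA1). The labels give 50 nM and 72 h after transfection for siFOXA1, and neither for siNT. Each group had 2 libraries. Sequencing depth is unknown, because the deposited lists hold peaks and no read numbers.

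The question for FOXA1 was whether its binding sites change on androgen receptor blockade and in resistant cells. FOXA1 had 63449 ± 9670 peaks (SD, n = 2) in untreated LNCaP, 71876 ± 9370 after 48 h of enzalutamide and 78664 ± 3359 in LNCaP-42D. The geometric mean was 1.25-fold higher in LNCaP-42D than in untreated cells, and the trend over the states did not pass the exact permutation test (p = 0.111, adjusted p = 0.139 over 5 tests, 6 libraries, two-sided, smallest possible p 0.0222). Reproducible regions numbered 53754, 61164 and 70700. A common set of 36019 regions was found in all 3 states.

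At 48 h, 12627 FOXA1 regions were gained (20.6% of 61164, 95% Wilson interval 20.3 to 20.97) and 8832 were lost (16.4% of 53754, 16.1 to 16.7). The highest count from the other splits of these 4 libraries was 2660. Such splits count only regions called in both states. In LNCaP-42D against untreated cells, 24175 regions were gained (34.2% of 70700) and 11664 lost (21.7%), against at most 941 in the other splits. LNCaP-42D differed from treated LNCaP by 15307 gained and 9705 lost regions, with at most 1356 in the other splits. In lists of equal length, 9054 regions were gained and 10371 lost at 48 h, and LNCaP-42D had 14983 gained and 14430 lost regions against untreated cells. Equal peak numbers draw gains and losses together, so the order of these counts does not test whether gains exceed losses. With a replicate omitted, all peaks of the lone library counted as its group's regions, and absence was judged on that library alone. Counts rise by this rule, so losses above gains do not test their balance. Without untreated FOXA1 replicate 1, 13841 regions were gained and 16003 lost at 48 h. Without treated replicate 1, 16578 were gained and 18152 lost in LNCaP-42D against treated cells. Respectively, these omissions also gave 20233 lost regions in LNCaP-42D against untreated cells and 24048 gained regions at 48 h. Most changed regions were weak within their lists. At 48 h, 44.2% of regions in the weakest quartile of fold enrichment were gained and 1.29% in the strongest.

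Several strong regions were also gained or lost. The best-ranked FOXA1 region gained at 48 h, chromosome 11 from 38229735 to 38230269, had an authors' fold enrichment of 63.1 and 64.8 in the treated replicates and no peak in untreated cells. Its folds in LNCaP-42D were 5.49 and 6.44. A region on chromosome 7 from 79204838 to 79205394 was gained at 48 h with folds of 52.8 and 56.4 and had folds of 50.9 and 61.98 in LNCaP-42D. The best-ranked lost region, chromosome 15 from 84331980 to 84332563, had folds of 86.1 and 87.2 in untreated cells, no peak at 48 h, and folds of 11.3 and 17.0 in LNCaP-42D. In LNCaP-42D, the region on chromosome 16 from 10257497 to 10258311 had folds of 115 and 122 and no peak in any FOXA1 list of LNCaP. The region on chromosome 5 from 45359579 to 45360287 was absent from untreated cells, had folds of 30.1 and 30.5 at 48 h, and 111 and 113 in LNCaP-42D.

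Regions gained at 48 h were often present in the resistant line, whose libraries took no part in selecting them. Of the 12627 FOXA1 regions gained at 48 h, 56.4% (55.5 to 57.2) were reproducible in LNCaP-42D, against 87.2% (86.8 to 87.5) of the 41193 regions kept from untreated cells. Of the 8832 regions lost at 48 h, 18.4% (17.6 to 19.2) were reproducible in LNCaP-42D, against 87.2% of kept regions. Kept regions were stronger, with a median fold in replicate 1 of 16.6 against 8.06 for gained regions. LNCaP-42D had 81039 and 76289 FOXA1 peaks against 56611 and 70286 in untreated cells. Sites missed in the untreated lists could therefore be called in LNCaP-42D without a change in binding. No share was matched for list length.

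The FOXA1 changes in LNCaP-42D were uneven along the genome. On chromosome 13, 33.9% (31.9 to 36) of 1995 untreated regions were lost, and on chromosome Y 153 of 159 were lost (96.2%, 92.0 to 98.3). On chromosome X, 44.3% (42.6 to 46.1) of 3037 LNCaP-42D regions were gained. At 48 h, the lost shares were 16.4% on chromosome 13 and 21.4% on chromosome Y, and the gained share on chromosome X was 22.5%. Among 526 windows of 5 Mb with at least 40 regions, the median loss in LNCaP-42D was 20.4%. The windows of chromosome 13 that start at 55000001, 60000001 and 65000001 lost 66.0%, 60.7% and 60.3%. All 3 best-ranked lost regions lay on these chromosomes. One of them, chromosome 13 from 62523871 to 62524609, had folds of 80.7 and 84.4 in untreated LNCaP, 23.4 and 41.0 at 48 h and no peak in LNCaP-42D. ARNTL peaks also had a higher share on chromosome X in LNCaP-42D, 2.52% ± 0.243 (SD, n = 6), than in LNCaP, 1.49% ± 0.132 (n = 8). Copy number was not measured, so on chromosomes 13, X and Y it cannot be separated from a change in FOXA1 binding.

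**Figure D1:**
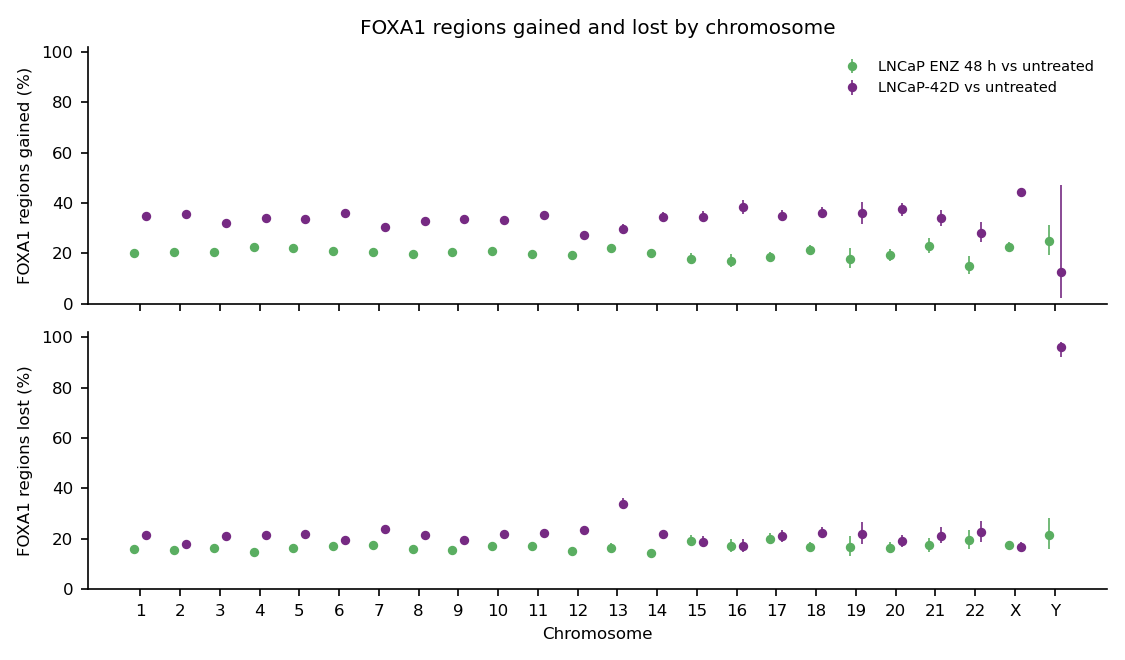
Percent of FOXA1 regions gained (top, of the later state's regions) and lost (bottom, of untreated regions) on each chromosome, for LNCaP after 48 h of enzalutamide and for LNCaP-42D, with 95% Wilson intervals. Chromosomes 13 (33.9%) and Y (96.2%) stand above the other chromosomes in the lost share of LNCaP-42D, and chromosome X (44.3%) in the gained share.

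ARNTL was mapped in the same states, which compares the sites of a clock factor before treatment, on the drug and in resistant cells. ARNTL had 2968 ± 1433 peaks (SD, n = 2) in untreated LNCaP, 6068 ± 1612 at 48 h and 11118 ± 5255 in LNCaP-42D. The geometric mean was 2.14-fold higher at 48 h and 3.76-fold higher in LNCaP-42D. The trend on the log2 scale reached the smallest p that the exact permutation test allows (p = 0.0222, 6 libraries) and did not pass after adjustment over 5 tests (adjusted p = 0.111). The unadjusted call ended without untreated replicate 1 (log2 difference 1.40 in place of 1.91, exact p = 0.133) and without LNCaP-42D replicate 2 (1.41, exact p = 0.2). Omission of a treated replicate (exact p = 0.0667) and a replicate block (exact p = 0.0556) leave the difference of 1.91 as it is and gave the smallest p these designs allow, so neither tests the call. Replicates within a group differed in list length by up to 2.04-fold.

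**Figure D2:**
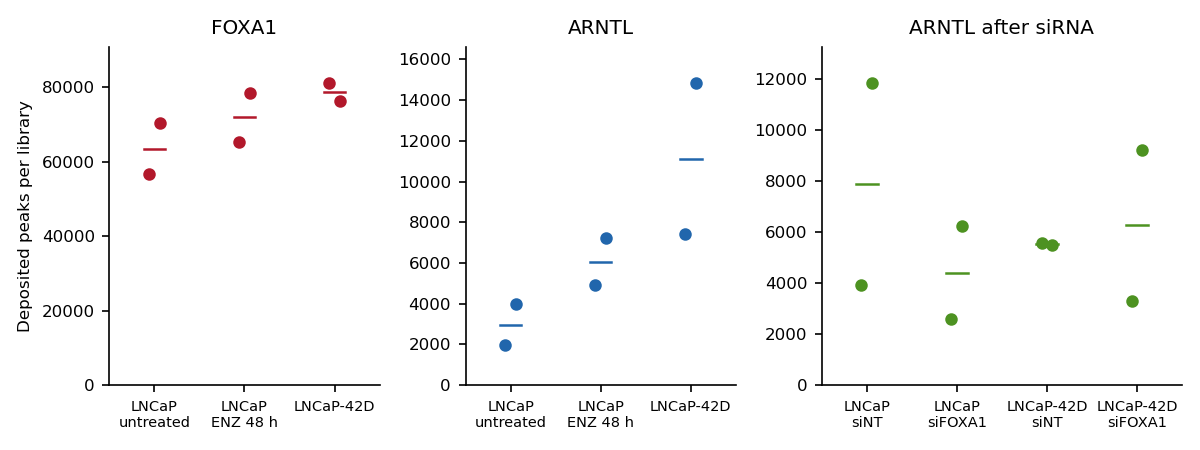
Number of deposited peaks per library (points) and group mean (line) for FOXA1, for ARNTL in untransfected cells and for ARNTL after siRNA, with 2 libraries per group. Mean ARNTL peak numbers are 2968, 6068 and 11118 over the states, while the siRNA groups overlap.

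ARNTL regions were mostly gained in the full lists. At 48 h, 1407 of 4390 reproducible regions were gained (32.1%, 30.7 to 33.4) and 86 of 1854 were lost (4.64%, 3.77 to 5.69), with at most 316 in the other splits, above the lost count. LNCaP-42D had 4198 gained regions of 7075 (59.3%, 58.2 to 60.5) and 164 lost against untreated cells, with at most 354 in the other splits, again above the lost count. Against treated LNCaP, 2589 regions were gained and 508 lost, with at most 877 in the other splits, so none of the 3 lost counts exceeded its splits. The other splits count only regions called in both states, so the shorter lists limit their counts. They do not test the gains. In lists of equal length, 171 regions were gained and 193 lost at 48 h, and 425 gained and 417 lost in LNCaP-42D against untreated cells. Equal peak numbers draw gains and losses together, so this balance does not test whether gains exceed losses. Omission of single libraries raised these counts, as the rule for a lone library does. Without untreated replicate 1, the losses were 590 at 48 h and 627 in LNCaP-42D, and without untreated replicate 2 the gains at 48 h were 2623. Without treated replicate 1, 3861 regions were gained at 48 h and 1338 lost in LNCaP-42D against treated cells, and without treated replicate 2 the losses at 48 h were 130. Without LNCaP-42D replicate 1 the gains were 11487 against untreated and 8767 against treated cells, and without replicate 2 the losses were 270 and 1080. Of the 1407 regions gained at 48 h, 55.4% (52.8 to 58.0) were reproducible in LNCaP-42D, against 89.5% of the 1711 kept regions. These shares were not matched for list length, and the LNCaP-42D lists were longer than the untreated ones.

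The best-ranked ARNTL region gained at 48 h, chromosome 10 from 76440173 to 76440476, had folds of 22.4 and 29.5 and was also called for FOXA1 at 48 h (24.1 and 26.0), with neither factor called there in untreated cells. A region on chromosome 11 from 6557621 to 6558196 was gained for ARNTL with folds of 19.2 and 21.1, at a site that FOXA1 already occupied in untreated cells (21.8 and 27.1). Another gained region, chromosome 11 from 120700837 to 120701204, had ARNTL folds of 16.7 and 23.9 and no FOXA1 peak in any state. The best-ranked lost region, chromosome 3 from 73853377 to 73853746, had ARNTL folds of 21.5 and 28.5 in untreated LNCaP, no peak at 48 h, and folds of 21.8 and 23.7 in LNCaP-42D. FOXA1 was called at this region in untreated LNCaP and in LNCaP-42D and not at 48 h. In LNCaP-42D the best-ranked gained region, chromosome 9 from 19557224 to 19557720, had ARNTL folds of 50.7 and 52.2 and FOXA1 folds of 76.2 and 76.3, and no LNCaP library had a peak of either factor there. The gained region on chromosome 4 from 166795648 to 166796402 had ARNTL folds of 37.1 and 40.5 and no FOXA1 peak. The best-ranked lost region, chromosome 13 from 114280004 to 114280759, had folds of 39.9 and 48.7 in untreated LNCaP and no peak in any LNCaP-42D library.

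The next question was how far ARNTL binds where FOXA1 binds. Of the ARNTL peaks of a library, 46.8% ± 5.18 (SD, n = 2) overlapped a FOXA1 region of the same state in untreated cells, 53.7% ± 4.09 at 48 h and 58.7% ± 9.07 in LNCaP-42D. Shifted peaks overlapped FOXA1 regions at 1.01% to 1.60% in these 6 libraries. The trend of 11.9 percentage points between untreated and resistant cells did not pass the exact permutation test (p = 0.0889, adjusted p = 0.139, 6 libraries). Among the 1955 strongest peaks of each ARNTL list the shares were 43.4% ± 0.398, 42.4% ± 1.77 and 44.7% ± 3.87, a difference of 1.33 points (exact permutation p = 0.667). With FOXA1 lists of equal length as well, the difference was -2.51 points. In full ARNTL lists the difference was -0.979 points with the FOXA1 regions of untreated cells for every state, and 4.34 points with those common to all 3 states (exact permutation p = 0.489). With full lists and the FOXA1 regions of the same state, it was 18.4 points without LNCaP-42D ARNTL replicate 1 (exact permutation p = 0.0333), 5.53 without LNCaP-42D ARNTL replicate 2 and 7.87 without untreated FOXA1 replicate 1.

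**Figure D3:**
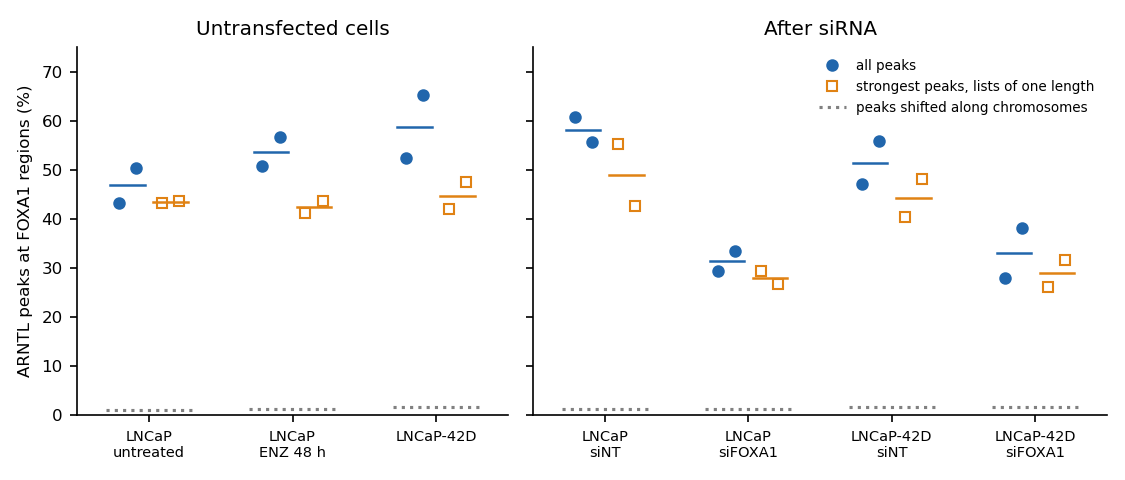
Percent of each library's ARNTL peaks that overlap a FOXA1 region of the same state, for all peaks (circles) and for the strongest peaks in lists of equal length (squares), with group means (lines) and the mean share after shifting peaks along chromosomes (dotted). The shares of the strongest peaks average 43.4%, 42.4% and 44.7% over the untransfected states, and all 4 siFOXA1 libraries lie below all 4 siNT libraries.

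ARNTL regions gained at 48 h lay more often at sites that FOXA1 occupied before treatment. Of the 1407 gained regions, 764 (54.3%) overlapped a FOXA1 region of untreated cells, against 702 (41.0%) of the 1711 regions kept from untreated cells. The odds ratio was 1.71 (95% interval 1.48 to 1.97), with a two-sided Fisher's exact p of 1.76e-13 (adjusted p = 5.29e-13 over 3 comparisons). By quartile of ARNTL fold enrichment, the odds ratios were 3.12, 3.99, 2.47 and 1.64 from weakest to strongest, and the last did not pass (Fisher's exact test, adjusted p = 0.121, 53 gained regions). In LNCaP-42D against untreated cells, 39.3% of 4198 gained and 41.5% of 1566 kept regions overlapped these FOXA1 regions (odds ratio 0.911, 0.809 to 1.02, Fisher's exact p = 0.123). Against treated LNCaP the shares were 35.7% of 2589 gained and 43.2% of 3270 kept regions (odds ratio 0.728, 0.655 to 0.810, Fisher's exact p = 4.67e-09, adjusted p = 7.01e-09). The direction in LNCaP-42D depended on the FOXA1 regions used. With those of LNCaP-42D itself, an alternative chosen after seeing the data, 55.2% of gained and 46.1% of kept regions overlapped them against untreated cells (odds ratio 1.44, 1.28 to 1.62, Fisher's exact p = 8.12e-10), and the odds ratio against treated LNCaP was 1.09 (0.979 to 1.203, Fisher's exact p = 0.127). With untreated FOXA1 regions but without LNCaP-42D replicate 1, the shorter list, these odds ratios turned to 1.40 and 1.11. The comparison with untreated cells passed without untreated ARNTL replicate 1 (0.805, Fisher's exact p = 1.03e-05), without LNCaP-42D replicate 2 (0.882, Fisher's exact p = 0.0356) and with lists of equal length (0.682, Fisher's exact p = 0.00266).

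FOXA1 knockdown was used to ask whether ARNTL binding depends on FOXA1. No FOXA1 list after siRNA was analysed here, so the remaining FOXA1 is not known. The share of ARNTL peaks at FOXA1 regions was 58.1% ± 3.63 (SD, n = 2) with siNT and 31.4% ± 2.94 with siFOXA1 in treated LNCaP, and 51.4% ± 6.20 and 33.0% ± 7.24 in LNCaP-42D. The difference was -26.8 percentage points in LNCaP and -18.4 in LNCaP-42D, and all 4 siFOXA1 libraries lay below all 4 siNT libraries. The exact permutation test within cell line gave p = 0.0556 (adjusted p = 0.139 over 5 tests), the smallest p this test can give. In LNCaP-42D the lower share was not a lower number in each library, since siFOXA1 replicate 2 had 3519 peaks at FOXA1 regions and the siNT libraries 2623 and 3061. Among the 2586 strongest peaks of each list the mean difference over the lines was -18.1 points, with the same p of 0.0556 in the exact permutation test. Peak numbers did not separate the siRNAs, with 7879 ± 5611 (siNT) and 4409 ± 2577 (siFOXA1) in LNCaP, and 5531 ± 65.1 and 6267 ± 4189 in LNCaP-42D (exact permutation p = 0.5, 8 libraries). Without LNCaP siNT replicate 2 the mean log2 difference in peak number changed sign, from -0.38 to 0.018.

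Region by region, loss of ARNTL was concentrated at FOXA1 sites. In LNCaP, 1020 of 2207 siNT regions at FOXA1 regions were lost after siFOXA1 (46.2%, 44.1 to 48.3), against 70 of 1499 elsewhere (4.67%, 3.71 to 5.86). In LNCaP-42D, 881 of 1988 were lost at FOXA1 regions (44.3%, 42.1 to 46.5) and 129 of 2071 elsewhere (6.23%, 5.27 to 7.35). The odds ratios were 17.5 (13.6 to 22.6, Fisher's exact p = 2.18e-192) and 12.0 (9.82 to 14.6, Fisher's exact p = 2.16e-188). The odds ratio was above 1 in each quartile of peak strength, from 12.2 to 26.0 in LNCaP and from 8.23 to 90.4 in LNCaP-42D. It moved most without LNCaP siNT replicate 1 (3.81) and without LNCaP-42D siNT replicate 2 (4.96). It was also lower without siFOXA1 replicate 2 in LNCaP (8.32) and in LNCaP-42D (5.77). With summits within 100 bp it was 7.39 and 6.36, and with loss defined as absence from either siFOXA1 replicate 8.43 and 5.70.

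**Figure D4:**
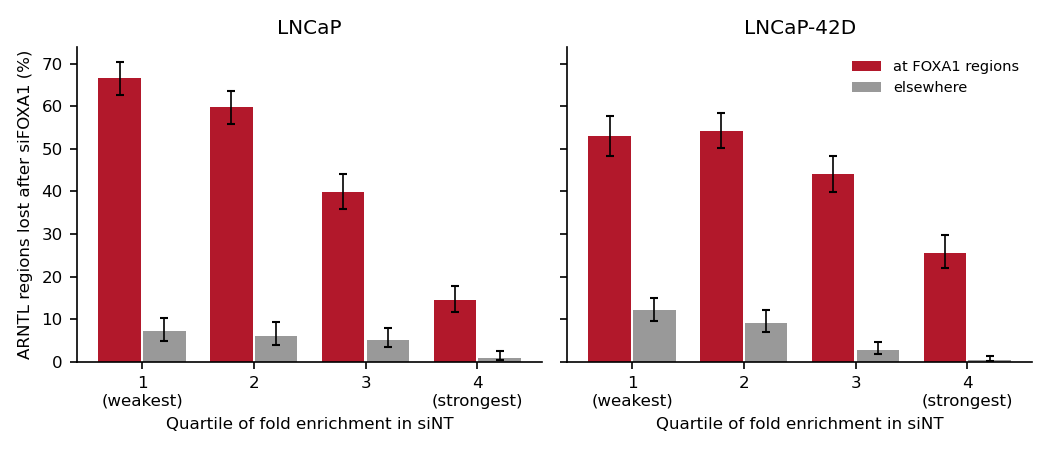
Percent of reproducible siNT ARNTL regions with no peak in either siFOXA1 library, at FOXA1 regions and elsewhere, by quartile of the authors' fold enrichment in the siNT lists, with 95% Wilson intervals. Losses at FOXA1 regions run from 66.6% in the weakest to 14.6% in the strongest quartile in LNCaP and from 53.0% to 25.6% in LNCaP-42D, above those elsewhere in each quartile.

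In total 1090 ARNTL regions were lost and 248 gained after siFOXA1 in LNCaP, and 1010 were lost and 757 gained in LNCaP-42D. The other splits of the same libraries gave up to 1779 in LNCaP, where siNT replicate 2 had 11846 peaks and siNT replicate 1 had 3911, and up to 451 in LNCaP-42D. Neither LNCaP total exceeded those splits. In lists of equal length, 450 regions were lost and 391 gained in LNCaP, and 545 and 538 in LNCaP-42D. Here too, equal peak numbers draw gains and losses together. Without siFOXA1 replicate 1, the shorter list in each line, all peaks of siFOXA1 replicate 2 counted as regions. This rule raises gains, so the order that it gave does not test their balance with losses. There were 1247 gained and 1099 lost in LNCaP and 5003 gained and 1022 lost in LNCaP-42D. In LNCaP, 6861 regions were lost without siNT replicate 1 and 2071 without siFOXA1 replicate 2, and without siNT replicate 2, 784 were gained and 1253 lost. In LNCaP-42D, losses were 1929 and 1774 without siNT replicates 1 and 2 and 1979 without siFOXA1 replicate 2. The best-ranked lost region in LNCaP, chromosome 10 from 98356339 to 98356791, had ARNTL folds of 18.4 and 23.4 with siNT and no peak with siFOXA1 in either line, and FOXA1 folds of 54.8 and 56.0 at 48 h. In LNCaP-42D the best-ranked lost region, chromosome 3 from 24181202 to 24181878, had folds of 48.1 and 51.4 with siNT and no peak with siFOXA1. In LNCaP this region was still called after siFOXA1, with folds of 8.20 and 14.2 against 35.4 and 56.2 with siNT. The region on chromosome 16 that was new for FOXA1 in LNCaP-42D had ARNTL folds of 22.2 and 23.1 with siNT and no ARNTL peak with siFOXA1. The ARNTL region on chromosome 4 without a FOXA1 peak had folds of 23.8 and 43.4 after siFOXA1 in LNCaP-42D.

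Of the 248 ARNTL regions that appeared after siFOXA1 in LNCaP, 16.9% (12.8 to 22.1) lay at FOXA1 regions, against 32.7% (30.4 to 35.0) of kept regions. In LNCaP-42D the shares were 24.4% (21.5 to 27.6) of 757 and 28.9% (27.0 to 30.9). The best-ranked of them in LNCaP, chromosome 3 from 73853322 to 73853722, had folds of 28.3 and 38.4. It overlaps the region that ARNTL lost at 48 h of enzalutamide. Regions on chromosome 16 from 1895800 to 1896260 and on chromosome 17 from 34245708 to 34246057 were called in both siFOXA1 libraries of both lines and in no other library.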

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

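The difference between the cell lines described here was tested after the values of each line had been seen. ARNTL regions at FOXA1 regions were lost after siFOXA1 more often than those elsewhere, and the odds ratio differed between LNCaP (17.5) and LNCaP-42D (12.0). The ratio of these odds ratios was 1.46 (95% interval 1.06 to 2.02 over regions, which are not replicates). The order of the lines turned in the stronger quartiles of peak strength, with overlapping 95% intervals. The odds ratios were 12.2 (7.55 to 19.8) in LNCaP and 27.0 (15.5 to 47.3) in LNCaP-42D in quartile 3. In quartile 4 they were 17.7 (6.41 to 48.8) and 90.4 (22.2 to 368), resting on 4 of 419 and 2 of 527 regions lost elsewhere. At the level of libraries, the change in the share of ARNTL peaks at FOXA1 regions differed between the lines by 8.35 percentage points. The exact permutation test of that difference gave p = 0.722. It exchanges siRNA labels within each line and so assumes no siRNA effect in either line. Because the share was lower after siFOXA1 in both lines, this p cannot tell whether the lines differ. Omissions were set side by side by replicate number, which is all that replicates of the lines share. Without siNT replicate 1 the odds ratios were 3.81 in LNCaP and 8.71 in LNCaP-42D, which turned the order. They were 17.8 and 4.96 without siNT replicate 2, 17.5 and 11.3 without siFOXA1 replicate 1, and 8.32 and 5.77 without siFOXA1 replicate 2. Those omissions kept the order.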

How the results depend on the processing

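The alternatives were planned except the crossed block, the omission of chromosomes and the FOXA1 regions of the later state, which were chosen after seeing the data. Of 298 values under an alternative, 224 kept their direction and side of the threshold or stayed within 1.5-fold for a count, including permutation tests that could not pass by design. The stricter threshold changed none of 26 results, and neither overlap rule changed the direction or call of the 23 it applied to. The odds ratios of loss after siFOXA1 kept their call but moved, in LNCaP and LNCaP-42D, to 7.39 and 6.36 with summits within 100 bp and to 8.43 and 5.70 with loss as absence from either replicate. Equal length is void for peak numbers and for the balance of gains and losses. Promoter, motif and gene list alternatives were not run. Depth is unknown and limits every count of peaks. Where no reason is given, the cause was not tested.

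With lists of equal length, fewer weak peaks enter. Equal peak numbers also draw gains and losses together, so their balance is not tested by these counts. FOXA1 gains and losses were 9054 and 10371 at 48 h, and gains in LNCaP-42D against untreated cells were 14983. ARNTL gains and losses were 171 and 193 at 48 h and 425 and 417 in LNCaP-42D against untreated cells, and gains against treated cells were 364. After siFOXA1, LNCaP had 391 gains and 450 losses and LNCaP-42D 545 losses. The trend in the share of ARNTL peaks at FOXA1 regions reversed to -2.51 percentage points. The odds ratio for ARNTL regions gained in LNCaP-42D against untreated cells at FOXA1 regions became 0.682 (Fisher's exact p = 0.00266).

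Other FOXA1 regions were tried on full lists. The trend in the share of ARNTL peaks at FOXA1 regions reversed to -0.979 percentage points with those of untreated cells throughout and was 4.34 with those common to all 3 states. With those of the later state, the odds ratio for ARNTL regions gained in LNCaP-42D reversed to 1.44 against untreated and to 1.09 against treated cells.

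A replicate block leaves the ARNTL peak number trend at its log2 difference of 1.91. Its smallest exact permutation p is 0.0556 for trends, which this trend had, and 0.125 for siRNA, so no call could pass and the block tests none. The replicates share only a number. The correlation of their deviations over regions lay between -0.246 and 0.0401. Counts within a single pair of libraries are larger because reproducibility is not required. For the pair numbered 1, FOXA1 gains were 21775 at 48 h, 38882 in LNCaP-42D against untreated and 29406 against treated cells. ARNTL gains and losses were 3138 and 152 at 48 h and 3912 and 1408 in LNCaP-42D against treated cells, with 302 losses against untreated cells. After siFOXA1 this pair had 926 gains and 2264 losses in LNCaP and 3206 losses in LNCaP-42D. For the pair numbered 2, FOXA1 gains and losses at 48 h were 25504 and 17110, losses in LNCaP-42D against untreated cells were 22914, and against treated cells 20271 regions were gained and 22104 lost, turning the order. ARNTL gains and losses were 3921 and 684 at 48 h, 11542 and 646 in LNCaP-42D against untreated cells and 9075 and 1382 against treated cells. After siFOXA1 they were 1271 and 6905 in LNCaP and 5730 and 1945 in LNCaP-42D, where the order turned. In the crossed block for ARNTL in LNCaP-42D against untreated cells, tried because the correlation was -0.184, gains and losses were 13107 and 194 for untreated replicate 1 with LNCaP-42D replicate 2, and 4539 and 1093 for the other pairing.

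Leaving out each replicate in turn makes a group's regions those of a lone library and judges absence on that library alone. Counts rise by this rule, so a turned order does not test the balance of gains and losses. FOXA1 gains and losses then ranged from 13841 to 24048 and from 9546 to 16003 at 48 h, and losses in LNCaP-42D from 12549 to 20233 against untreated and from 10723 to 18152 against treated cells. Losses exceeded gains at 48 h without untreated replicate 1 and in LNCaP-42D against treated cells without treated replicate 1, turning the order. ARNTL gains and losses ranged from 1463 to 3861 and 101 to 590 at 48 h, from 4245 to 11487 and 169 to 627 in LNCaP-42D against untreated cells, and from 2776 to 8767 and 522 to 1338 against treated cells. After siFOXA1, gains and losses ranged from 255 to 1247 and 1099 to 6861 in LNCaP, and from 808 to 5003 and 1022 to 1979 in LNCaP-42D, and gains exceeded losses in both lines without siFOXA1 replicate 1, turning the order. The log2 trend in FOXA1 peak number, 0.318 with all libraries, ranged from 0.162 without untreated replicate 1 to 0.474 without untreated replicate 2. The log2 trend in ARNTL peak number ranged from 1.40 to 2.42, and lost its call without untreated replicate 1 and without LNCaP-42D replicate 2. Without a treated ARNTL replicate the smallest exact permutation p is 0.0667, so neither ARNTL trend could pass, and no siRNA permutation test could pass in any setting. The log2 difference after siFOXA1 ranged from -0.78 to 0.018. The trend in the share at FOXA1 regions ranged from 5.53 to 18.4 points and passed only without LNCaP-42D ARNTL replicate 1 (exact permutation p = 0.0333). The difference in this share between siFOXA1 and siNT ranged from -25.1 to -20.02 points. The odds ratio for gained ARNTL regions at FOXA1 regions ranged from 0.805 to 1.40 in LNCaP-42D against untreated cells and from 0.687 to 1.11 against treated cells, with the values above 1 both from omitting LNCaP-42D ARNTL replicate 1. At 48 h it ranged from 1.48 to 2.05 and kept its call. The odds ratios of loss after siFOXA1 ranged from 3.81 to 18.0 in LNCaP and from 4.96 to 12.3 in LNCaP-42D.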

Other observations

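The tests of list length, of peak strength for the siRNA share, of copy number and of fewer peaks called were chosen only after the results were seen, and the shares at gained FOXA1 regions and in siNT libraries were not planned. ARNTL regions gained with treatment were also called in the siNT libraries, which took no part in selecting them. Of the 1407 regions gained at 48 h, 1316 (93.5%, 95% Wilson interval 92.1 to 94.7) had a peak in at least 1 siNT library of treated LNCaP, against 99.4% of kept regions. In siNT replicate 1, the shorter list, it was 43.4% against 89.2%, and in replicate 2, with 11846 peaks, 92.3% against 99.4%. In LNCaP-42D, 2881 of 4198 regions gained against untreated cells did (68.6%, 67.2 to 70.0), against 96.9% of kept regions. Gained ARNTL regions lay at gained FOXA1 regions more often than kept ones, with 3.91% against 0.818% at 48 h (Fisher's exact adjusted p = 4.46e-09) and 11.3% against 3.38% in LNCaP-42D against untreated cells (Fisher's exact adjusted p = 1.01e-23). Of all FOXA1 regions, 20.6% were gained at 48 h and 34.2% in LNCaP-42D. Gained FOXA1 regions held a smaller part of the gained ARNTL regions at FOXA1 sites, 55 of 874 at 48 h and 475 of 2317 in LNCaP-42D. Kept ARNTL regions were called in untreated cells, where gained FOXA1 regions had no peak. This selection alone can lower the share among kept regions. None of these shares was matched for peak strength.

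Some named regions showed such a joint gain in LNCaP-42D, and others did not. The gained ARNTL regions on chromosome 4 from 166795648 to 166796402 and on chromosome 21 from 44865978 to 44866747 had no FOXA1 peak. The region on chromosome 9 from 19557224 to 19557720, called for neither factor in LNCaP, had ARNTL folds of 30.8 and 45.1 with siNT and 9.07 and 12.1 with siFOXA1. The region on chromosome 16 from 10257497 to 10258311 had ARNTL folds of 32.5 and 38.7 in untransfected LNCaP-42D. The region on chromosome 3 from 73853377 to 73853746 was no joint gain, since both factors were called there in untreated LNCaP. Lost for ARNTL at 48 h, it had ARNTL folds of 28.0 and 41.1 after siFOXA1 in LNCaP-42D.

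Regions that appeared after siFOXA1 were compared between the lines. Of the 248 in LNCaP, 94 were reproducible with siFOXA1 in LNCaP-42D, and 68 of these (72.3%) were absent from both siNT libraries there. For 1508 regions not new in LNCaP the share was 7.49%, an odds ratio of 32.3 (95% interval 19.8 to 52.8). Independent appearance in each line cannot be told apart from a shared response, because sites that the related lines share with siNT give a ratio above 1 as well.

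ARNTL regions at FOXA1 sites with no peak before treatment were lost after siFOXA1 in 63.5% of 1044 cases in LNCaP, against 30.7% of 1163 regions called before treatment, and in 51.0% of 918 against 38.6% of 1070 in LNCaP-42D. Away from FOXA1 sites the shares were 16.4% of 262 against 2.18% of 1237 in LNCaP. In LNCaP-42D they were 10.6% of 846 against 3.18% of 1225. The pattern was therefore not particular to FOXA1 sites. At FOXA1 sites, the Mantel-Haenszel odds ratio within quartiles of peak strength was 2.08 (95% interval 1.70 to 2.54) in LNCaP and 1.18 (0.974 to 1.44) in LNCaP-42D. The LNCaP value argues against strength differences between quartiles as the whole source there. Strength differences within a quartile were not tested. In LNCaP-42D, peak strength stays open altogether.

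The share of ARNTL peaks at FOXA1 regions was lower after siFOXA1 in both lines. List length is argued against, since the mean difference was -18.1 percentage points with lists of equal length. So is peak strength, with a lowest odds ratio of loss over the quartiles of both lines of 8.23 (95% interval 6.02 to 11.3). ARNTL signal from open chromatin at FOXA1 regions cannot be told apart from recruitment by FOXA1, because both predict that strong FOXA1 regions hold ARNTL more often, as 14.3% of the top and 1.32% of the bottom decile at 48 h did. That ARNTL may need FOXA1 at these sites is a hypothesis.

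The share of ARNTL peaks at FOXA1 regions was higher in later states in full lists. With ARNTL lists of equal length the difference between resistant and untreated cells was 1.33 percentage points, against 11.9 in full lists. ARNTL list length is therefore a candidate explanation, but not the only one. With full ARNTL lists and the FOXA1 regions of untreated cells for every state the difference was -0.979, so the rise also depended on the FOXA1 set used. Whether the lists are longer through more bound sites or through depth was not tested, as depth is unknown.

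FOXA1 regions were lost on chromosomes 13 and Y in LNCaP-42D. Fewer peaks called in that line is argued against by the 19 of 21 other autosomes with more FOXA1 peaks in both LNCaP-42D libraries than in both untreated libraries. A copy number difference between the lines may contribute on chromosome 13, since the share there of ARNTL peaks with no FOXA1 peak in any library was lower in LNCaP-42D (1.49% ± 0.0777, SD, n = 6) than in LNCaP (1.79% ± 0.225, n = 8, exact permutation within siRNA condition, p = 0.0167), with LNCaP siNT replicate 1 (1.49%) and siFOXA1 replicate 1 (1.57%) inside the LNCaP-42D range; untreated and treated LNCaP were pooled as the untransfected condition, and line and treatment state cannot be separated for LNCaP-42D. Over all ARNTL peaks the mean difference was -0.712 percentage points and without FOXA1 sites -0.276, so a change in FOXA1 binding stays open. Copy number was not measured. On chromosome Y, with at most 12 ARNTL peaks a library, the shares were 0.110% in LNCaP and 0.0199% in LNCaP-42D (exact permutation within siRNA condition, p = 0.00185). With no FOXA1 peak in any library they were 0.0632% and 0% (same permutation test, p = 0.0278). Untreated LNCaP replicate 2 and LNCaP siNT replicate 1 also had 0%. FOXA1 had 8 to 9 peaks on chromosome Y in the LNCaP-42D libraries and 167 to 261 in those of LNCaP. With both antibodies lower, a copy number difference may contribute on chromosome Y as well. On chromosome X the ARNTL share was higher in LNCaP-42D (2.52% against 1.49%), so copy number stays open for the FOXA1 gains there too. Without chromosomes 13, X and Y, chosen after seeing the data, LNCaP-42D had 22237 gained and 10545 lost FOXA1 regions against untreated cells.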
